A study of Mus musculus with 4 samples.

How the data were processed

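RNA was measured in endothelial cells sorted by flow cytometry from the hearts of young mice on a C57BL/6 background, labelled as freshly isolated. The labels give 2 genotypes with 2 libraries each. The labels do not expand ECp53KO, which is read here as a knockout of p53 in endothelial cells because the series title names endothelial p53, and the Ctrl libraries are labelled wild type. The libraries are named below by their group and the number in their title: ECp53KO_170, ECp53KO_172, Ctrl_178 and Ctrl_182. Nothing in the labels says in so many words that each library came from a separate mouse, so the p-values of single genes measure only the spread between these libraries. The camera test of gene lists and Fisher's exact test, used below, compare genes with other genes, which are not independent replicates. The labels also do not say which exons of the gene were deleted.

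Per the labels' protocols, libraries were made with a TruSeq kit that selects polyadenylated RNA and keeps no strand, and were sequenced in pairs of short reads on an Illumina instrument. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart. The submitters' processing notes name bcl2fastq 2.17, FastQC 0.11.5, Trimmomatic 0.36, TopHat2 2.1.0 and Cufflinks 2.2.1 and the build mm10, without saying what each was used for. The gene annotation, any filter, and whether the libraries were quantified together are not given in the sources used here.

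The authors deposited a table of FPKM values (fragment counts scaled by gene length and by sequencing depth), with 24346 gene symbols and 4 columns that match the 4 libraries by title. FPKM are not counts, so no count test was run. The FPKM columns sum to between 603783 and 732051. Symbols were matched to RefSeq's gene table for GRCm38.p6, of which mm10 is the browser name: 23143 matched by symbol, 1086 by a synonym and 117 not at all. Positions printed are from that table. The fixed lists hold 19 genes that the table does not, among them every mitochondrially encoded gene.

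The depth of each library was estimated from the most frequent product of FPKM and transcript length among low values, sought within a fixed range. It was assumed to stand for 1 fragment, since a gene counted in whole fragments takes values that are multiples of 1 fragment. Over 1037 genes with a single GENCODE M21 transcript longer than 2000 nucleotides and no value of 0.5 FPKM or more, this gave about 11400000 and 9900000 fragments in ECp53KO_170 and ECp53KO_172, and 10900000 and 22500000 in Ctrl_178 and Ctrl_182. On a transcript of 2 kb, 1 fragment is then worth 0.0438, 0.0506, 0.0457 and 0.0222 FPKM in these libraries. An exact 0 in such a table can be a failed estimate. Rpl26, which encodes a ribosomal protein, was listed at 20.5 FPKM in ECp53KO_170, 0.000682 in ECp53KO_172, 22.0 in Ctrl_178 and 2.00 in Ctrl_182. Values of 0 are therefore given as listed, and no fold of a single gene against them is printed. Loci of microRNAs, small nucleolar RNAs and other small RNAs took between 19.2% and 22.5% of each library's summed FPKM. Division by so short a length gives a large FPKM for few fragments.

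Values were analysed as log2(FPKM + 1) in genes with a mean of at least 1 FPKM over the 4 libraries, which left 11332 genes. Fold changes are ECp53KO minus Ctrl on that scale, which understates the change of genes with low values. The test was limma 3.58.1 in R 4.3.3 with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit has 2 residual degrees of freedom, to which the shared variance estimate adds 3.15. No covariate was used. An exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.333 and was not used. With 2 against 2, chance alone leaves 33.3% of genes without overlap between the groups, and 35.9% of the tested genes had none.

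Before the data were examined, 43 gene lists were fixed (pathways, markers of cell types that heart tissue could contribute to the sort, and technical lists), as were the tests, the alternatives and the rule for naming genes. Lists were tested with limma's camera at a preset correlation between genes of 0.01. Adjustment ran over the 36 pathway and marker lists with at least 2 tested members, and separately over the 2 technical lists that could be tested. A test with an estimated correlation and fry, which asks whether a list's genes move on balance in one direction, stand beside it. No list passed either of these after adjustment. The few residual degrees of freedom limit both, so a call lost there does not by itself show that members are correlated. Members of each list were also counted after adjustment over the list alone. Genes on the X and Y chromosomes that show the sex of the mice are given as values.

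The named genes are Trp53; up to 10 genes per direction with the largest fold among those past the threshold with no overlap between groups, filled up to 5 by the smallest p where fewer passed; 8 p53 target genes in any case and up to 6 more that passed over the list alone; up to 4 members of each other list that passed over all genes, or up to 2 by the smallest p where none did; and the 2 most abundant members of a marker list. Predicted genes, Rik clones, small RNA loci, pseudogenes and sex-linked genes are passed over for the genes of largest fold. Any further gene is said to have been chosen after its values were seen.

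Alternatives set in advance were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, scaling by the median of ratios, quantile normalization, rescaling to TPM without erythroid and mitochondrially encoded genes, limma without the trend or with robust variance shrinkage, each library left out in turn, an adjusted p under 0.1, and limma's treat against a log2 fold change of 0.5. Added after the data were seen were a fit without small RNA loci (11103 genes, with 6.52 degrees of freedom added by the shared variance), the same without each library in turn, removal of each library's trend on transcript length, and a fit with Xist above 1 FPKM as a covariate. A fit without 1 library leaves a single library in its group, which is assumed to vary like the libraries of the other group. Transcript length is that of the longest GENCODE M21 transcript, which 96.4% of the genes in the fit without small RNA loci had.

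The fit was tested on simulated values with the spread of the real genes, in which 200 genes were shifted. Over all 11332 genes, 2% of shifts of log2 1 and 50% of shifts of log2 2 were recovered, with 1 false call. Without small RNA loci, over 11103 genes, these were 5% and 61%, with 2 false calls. A list shifted downwards was recovered in both, and 2 and 1 of 40 unshifted lists had an unadjusted camera p under 0.05. The simulated genes varied independently of each other, whereas estimated correlations within the real lists reached 0.94. The simulation therefore does not give the rate of false calls for lists of correlated genes. Figures were drawn with matplotlib from the tables of results.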

Results

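The series compares the transcriptome of heart endothelial cells labelled ECp53KO, read here as a knockout of p53 in endothelial cells (2 libraries), with that of wild-type controls (Ctrl, 2 libraries). The series title names a protective function of p53 in the endothelium against vascular malignancy. The cells were sorted from mice labelled young and are labelled as freshly isolated. Estimated depth was 9900000 to 11400000 fragments in ECp53KO_170, ECp53KO_172 and Ctrl_178, and 22500000 in Ctrl_182. All levels below are FPKM as deposited.

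The first question was whether the targeted transcript was reduced in the libraries labelled ECp53KO. Trp53, which encodes the transcription factor p53 (chromosome 11, 69580348 to 69591873, GRCm38), stood at 4.41 and 2.45 FPKM in ECp53KO_170 and ECp53KO_172 and at 52.1 and 28.8 FPKM in Ctrl_178 and Ctrl_182. The group means were 3.43 ± 1.39 and 40.5 ± 16.5 FPKM (SD, n = 2 each), 11.8 times higher in Ctrl. The log2 fold change was -3.20 ± 0.36 (SE). It did not pass adjustment over all 11332 genes (limma adjusted p = 0.146), and it passed in the fit without small RNA loci, chosen after the data were seen (limma adjusted p = 0.0127). Over the alternatives that kept all 4 libraries, the limma adjusted p of Trp53 ran from 0.0127 to 0.62. The genes on either side of it, Wrap53 (6.01 and 4.97 against 6.76 and 6.17 FPKM) and Atp1b2 (11 and 18.2 against 14 and 12.4 FPKM), chosen after their values were seen, had limma adjusted p-values of 0.870 and 0.948.

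Known transcriptional targets of p53 were lower as a group in the ECp53KO libraries. Of 40 measured targets, 35 had a negative fold change, and 27 were lower in both ECp53KO libraries than in either control. Over all tested genes 16.8% were lower in this way. The median log2 fold change was -0.38. The strongest differences were in Gdf15, Phlda3, Eda2r and Sesn2, and the cell cycle inhibitor Cdkn1a differed less. The list passed the camera test (adjusted p = 1.4e-14), but not after adjustment with an estimated correlation (adjusted p = 0.83, unadjusted p = 0.0397) or with fry (adjusted p = 0.245, unadjusted p = 0.0204).

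Of the 40 targets, 6 fell when adjusted over the list alone. By limma 0 passed over all genes, while 16 were lower and 0 higher at an unadjusted p under 0.05. Phlda3, which encodes an inhibitor of AKT signalling, averaged 8.81 ± 0.207 FPKM in ECp53KO and 48.0 ± 15.3 in Ctrl (SD, n = 2 each). Its log2 fold change was -2.28 ± 0.25 (SE), with a limma adjusted p of 0.0042 over the list alone. Eda2r, a receptor of the tumour necrosis factor family, averaged 3.11 ± 0.776 against 14.7 ± 1.15 FPKM, a log2 fold change of -1.94 ± 0.20, with the same limma adjusted p over the list. Gdf15, a secreted stress-induced cytokine, was listed at 0 and 0.319 FPKM in ECp53KO_170 and ECp53KO_172 and at 13.8 and 6.14 FPKM in Ctrl_178 and Ctrl_182 (limma adjusted p = 0.00618 over the list). Sesn2, a stress-induced regulator of mTORC1, averaged 0.877 ± 0.215 against 5.76 ± 1.79 FPKM. Trp53inp1, a p53-induced nuclear protein, averaged 5.36 ± 1 against 12.7 ± 0.661 FPKM, and the cyclin gene Ccng1 15.3 ± 0.828 against 27.6 ± 3.41 FPKM.

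The remaining targets named in advance did not pass over the list alone. Cdkn1a, which encodes p21, stood at 353 and 387 FPKM in ECp53KO and at 528 and 668 FPKM in Ctrl, with a log2 fold change of -0.68 ± 0.23 (limma adjusted p = 0.0913 over the list). Mdm2, which encodes the ubiquitin ligase that degrades p53, averaged 15.1 ± 3.30 against 22.5 ± 0.506 FPKM (limma adjusted p = 0.0913 over the list). The apoptosis effector Bax averaged 91.1 ± 12.5 against 170 ± 43.7 FPKM, and Zmat3 averaged 0.951 ± 0.191 against 3.52 ± 1.79 FPKM. With small RNA loci left out, 12 targets passed over the list alone, Bax and Zmat3 among them. The count of 6 was 1 without ECp53KO_170, 1 without ECp53KO_172, 2 without Ctrl_178 and 6 without Ctrl_182.

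**Figure D1:**
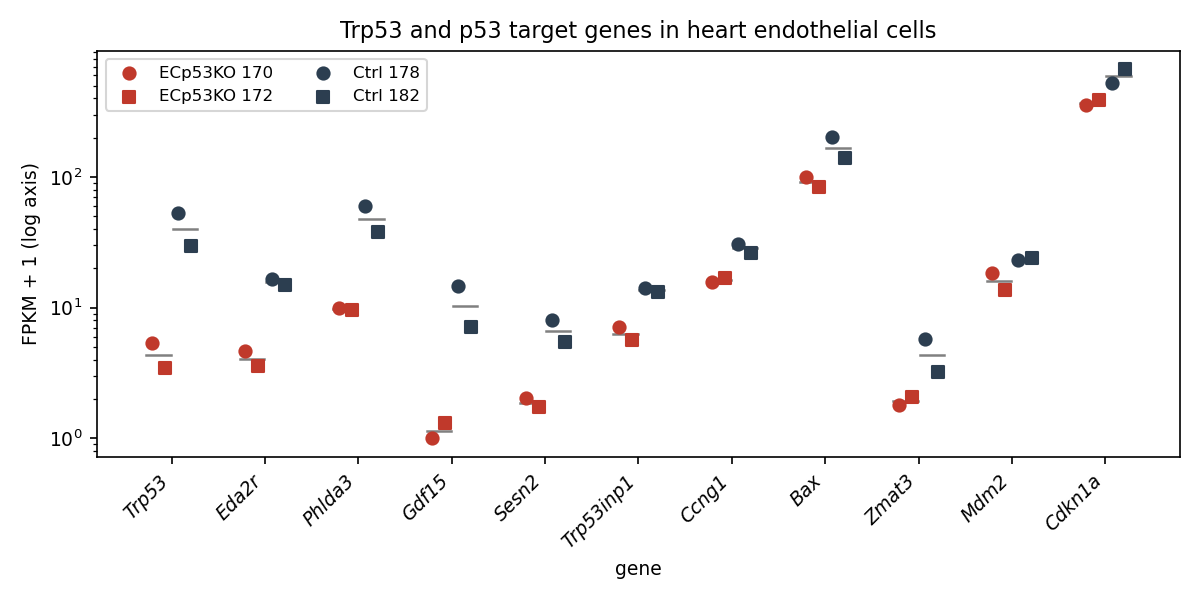
FPKM + 1 on a log axis for Trp53 and 10 p53 target genes, with 1 point per library (red ECp53KO, dark blue Ctrl) and a grey bar at the mean of the 2 log values. Both ECp53KO points lie below both Ctrl points for each gene shown, with Trp53 at 4.41 and 2.45 against 52.1 and 28.8 FPKM and Cdkn1a at 353 and 387 against 528 and 668 FPKM.

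Across all genes, few passed the test. Of 11332 genes, 3 were higher and 10 lower in ECp53KO, all with at least a fold of 2 on the log2(FPKM + 1) scale, while 223 and 319 had an unadjusted limma p under 0.05. Of the 13, 12 were small RNA loci, 2 higher and 10 lower, and each of these was listed at 0 in both libraries of a group. The higher ones were Snord4a (314 and 361 FPKM in ECp53KO, listed at 0 in Ctrl) and Mir6396 (28.8 and 66.2 FPKM). Among the lower ones Snord52 was listed at 0 in ECp53KO and at 2740 and 2668 FPKM in Ctrl_178 and Ctrl_182, and the locus Gm25500 at 0 against 1370 and 2668 FPKM. These loci were picked after their values were seen. The ratio of Snord52 to Gm25500 was 2 in Ctrl_178 and 1 in Ctrl_182 and both values are uncertain, since how reads are shared between such short loci is not given in the sources used here.

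Xaf1, an interferon-induced gene linked to apoptosis (chromosome 11, 72301461 to 72313733), was the remaining call. It rose from 31.8 ± 0.0236 FPKM in Ctrl to 136 ± 3.06 in ECp53KO (SD, n = 2 each), a log2 fold change of 2.06 ± 0.14 (limma adjusted p = 0.0251). Its log2 fold change lay between 1.96 and 2.09 under every alternative. The call was lost in 7 of the alternatives, among them each fit over all genes without a library (limma adjusted p = 0.0862 without ECp53KO_170, 0.0964 without ECp53KO_172, 0.288 without Ctrl_178 and 0.345 without Ctrl_182). With small RNA loci also left out, Xaf1 passed without each library in turn (limma adjusted p = 0.000838 to 0.00794).

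In the fit without small RNA loci, 3 genes were higher (Xaf1, Tlcd2 and AA465934) and 4 lower (Trp53, Phlda3, Eda2r and Gdf15), and 283 and 403 had an unadjusted limma p under 0.05. Tlcd2 averaged 20.8 ± 2.26 FPKM in ECp53KO and 4.98 ± 0.380 in Ctrl, a log2 fold change of 1.86 ± 0.17 (limma adjusted p = 0.0706 over all genes and 0.0127 without small RNA loci). The long noncoding RNA AA465934 stood at 89.2 and 40.8 FPKM against 1.83 and 2.63 FPKM, a log2 fold change of 4.26 ± 0.39 (limma adjusted p = 0.0717 and 0.00642). Both lie on chromosome 11, at 75468024 to 75470899 and 83291699 to 83294637. Xaf1, Tlcd2 and AA465934 are 2.72, 5.89 and 13.71 Mb away from Trp53. Of the genes named by their small p, Pcp4l1 (78.2 ± 11 against 37.1 ± 0.203 FPKM), Apoc1 (12.3 ± 2.30 against 4.86 ± 0.0382 FPKM) and Spsb1 (3.07 ± 0.431 against 9.02 ± 0.118 FPKM) passed in neither fit. Leaving out a library moved the counts of 3 higher and 10 lower to 18 and 13 without ECp53KO_170, 21 and 12 without ECp53KO_172, 1 and 58 without Ctrl_178, and 4 and 34 without Ctrl_182.

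**Figure D2:**
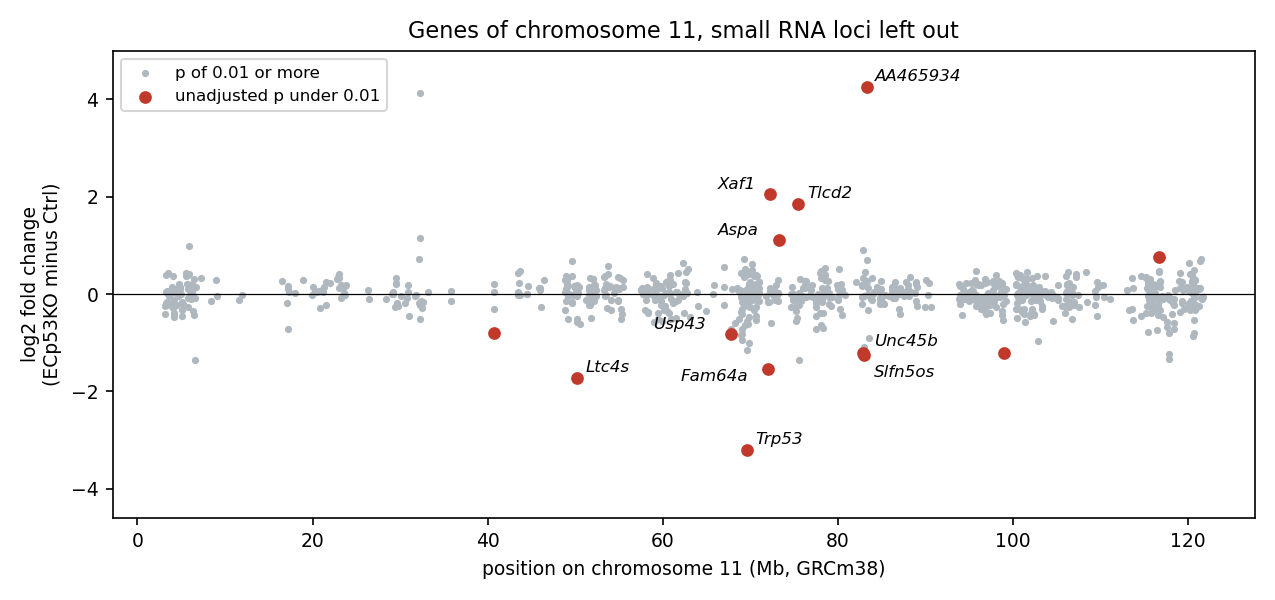
Log2 fold change (ECp53KO minus Ctrl) of each tested gene of chromosome 11 against its start in Mb (GRCm38), small RNA loci left out, with genes of unadjusted limma p under 0.01 in red. Labels mark those within 20 Mb of Trp53, among them Xaf1 (2.06), Tlcd2 (1.86) and AA465934 (4.26) above 0.

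Genes of the G2 phase and of mitosis were lower in ECp53KO. All 30 measured members had a negative fold change, 26 of them without overlap between the groups (16.8% of all tested genes were lower in this way). The median was -0.96 (camera adjusted p = 2.03e-21). The call was lost with an estimated correlation of 0.63 between members (adjusted p = 0.83, unadjusted p = 0.124) and with fry (adjusted p = 0.462, unadjusted p = 0.0812). By limma 0 members passed over all genes, 21 were lower at an unadjusted p under 0.05, and 14 fell when adjusted over the list alone, among them the cyclins Ccnb2 (3.17 ± 0.956 against 8.54 ± 1.29 FPKM) and Ccna2 (2.73 ± 0.292 against 7.22 ± 1.75 FPKM). Their levels were low throughout, with a mean log2(FPKM + 1) over the list of 1.25 and 1.40 in ECp53KO_170 and ECp53KO_172 and of 2.44 and 1.91 in Ctrl_178 and Ctrl_182. The count of 14 was 0 without ECp53KO_170, 0 without ECp53KO_172, 0 without Ctrl_178 and 24 without Ctrl_182. Genes of the G1/S transition and DNA replication did not pass (26 measured, median -0.08, camera adjusted p = 0.203), with Rfc4 at 7.02 ± 0.142 against 3.45 ± 0.257 FPKM and Chaf1a at 1.39 and 1.18 against 3.06 and 2.55 FPKM.

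Identity genes of the endothelium did not separate the groups. The pan-endothelial list had a median log2 fold change of -0.12 (25 measured, camera adjusted p = 0.515), with Cdh5, which encodes VE-cadherin, at 982 and 958 FPKM in ECp53KO and 1098 and 1022 FPKM in Ctrl. Capillary genes (median -0.06), arterial genes (-0.06), venous genes (-0.23) and lymphatic genes (-0.20) did not pass either, with camera adjusted p-values of 0.495, 0.495, 0.103 and 0.211. Fabp4 and Cd36, which serve fatty acid transport in capillaries, were the most abundant capillary genes, at 16876 to 21698 and 3164 to 3273 FPKM in ECp53KO and 14199 to 21598 and 2402 to 3952 FPKM in Ctrl. The endocardial genes were lower as a list (8 of 8 negative, median -0.38, camera adjusted p = 0.00157), with Foxc1 at 3.77 ± 0.777 against 6.10 ± 0.424 FPKM and Npr3 at 1.95 ± 0.0615 against 4.44 ± 2.09 FPKM, neither past the test. That call was lost with an estimated correlation (adjusted p = 0.83) and in the fits without ECp53KO_170 (camera adjusted p = 0.0625) or Ctrl_182 (0.11).

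Collagen and matrix genes were lower in ECp53KO as a list. Of 25 measured, 24 had a negative fold change and 13 were lower without overlap (16.8% of all tested genes were). The median was -0.56 (camera adjusted p = 3.17e-06, and adjusted p = 0.83 with an estimated correlation). By limma 0 passed over all genes or when adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05. The elastin gene Eln averaged 27.8 ± 11.3 against 53.9 ± 1.61 FPKM and the laminin gene Lamc1 66.5 ± 23.5 against 108 ± 15.7 FPKM. The mean level over the list was 3.74 in ECp53KO_170, 4.16 in ECp53KO_172, 4.57 in Ctrl_178 and 4.16 in Ctrl_182. Members have long transcripts (median 5564 nucleotides, against 3280 over all measured genes), and FPKM in ECp53KO_170 fell with transcript length relative to the other libraries (Spearman's rho -0.43 across genes, which are not independent replicates). With each library's length trend removed, the median of the list was -0.43 (camera adjusted p = 1.43e-05), and its median shift in ECp53KO_170 from the other 3 libraries was -0.58 in place of -0.79. Without Ctrl_178 the call was lost (median -0.29, camera adjusted p = 0.0701), and the median was -0.19 without ECp53KO_170 (0.027) and -0.85 without ECp53KO_172 (2.13e-07).

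Some lists of other cell types were higher in ECp53KO, at levels below those of the endothelial genes. The mean log2(FPKM + 1) was 2.48 to 2.98 over the pericyte and smooth muscle list and 8.07 to 8.17 over the pan-endothelial list. Pericyte and smooth muscle genes had 12 of 13 positive members and a median of 0.36 (camera adjusted p = 0.000744; adjusted p = 0.83 with an estimated correlation). Of these, 3 rose when adjusted over the list alone: the actin gene Acta2 (19 ± 3.20 against 8.76 ± 1.45 FPKM), Myl9 (21.3 ± 4.28 against 10.5 ± 1.38 FPKM) and Tagln (20.1 ± 4.13 against 11.3 ± 0.601 FPKM). Without ECp53KO_170 the list did not pass (median 0.14, camera adjusted p = 0.0512), and without ECp53KO_172 its median was 0.68. Cardiomyocyte genes had a median of 0.37 (15 of 19 positive, camera adjusted p = 0.00428; adjusted p = 0.83 with an estimated correlation), and summed to 583 FPKM in ECp53KO_170 against 343, 341 and 326 FPKM in ECp53KO_172, Ctrl_178 and Ctrl_182. The troponin gene Tnnc1 stood at 21.7 and 17.1 against 9.85 and 13.3 FPKM. Erythroid genes had a median of 1.88 (6 of 7 positive, camera adjusted p = 0.000672; adjusted p = 0.83 with an estimated correlation) and summed to 464 FPKM in ECp53KO_170, 98.4 in ECp53KO_172, 69.1 in Ctrl_178 and 42.3 in Ctrl_182, with the haemoglobin gene Hbb-b1, uncertain because it has near-identical copies, at 191, 55.4, 37.5 and 19.9 FPKM. Without ECp53KO_172 the cardiomyocyte median was 0.83. Without ECp53KO_170 the median was 0.04 for the cardiomyocyte list, which then did not pass (camera adjusted p = 0.780), and 0.55 for the erythroid list (0.0465).

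Nuclear-encoded genes of oxidative phosphorylation (37 of 40 positive, median 0.18, camera adjusted p = 0.00175) and, as a technical list, ribosomal protein genes (45 of 46 positive, median 0.32, camera adjusted p = 4.59e-06) were higher in ECp53KO. Both calls were lost with an estimated correlation of 0.89 and 0.94 (adjusted p = 0.83 and 0.813) and in the fit without ECp53KO_170, where the medians were -0.06 and 0.01 (0.48 and 0.63 without ECp53KO_172). By limma 0 members of either list passed over all genes or over the list alone, and 0 had an unadjusted p under 0.05. Members of both lists have short transcripts (median 1298 and 1124 nucleotides), and with the length trend removed the medians were 0.07 (camera adjusted p = 0.198) and 0.17 (8.68e-05). Ndufb10, a subunit of respiratory complex I, stood at 206, 142, 112 and 143 FPKM in ECp53KO_170 and ECp53KO_172 and Ctrl_178 and Ctrl_182, and Rps23 at 932, 597, 524 and 578 FPKM.

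**Figure D3:**
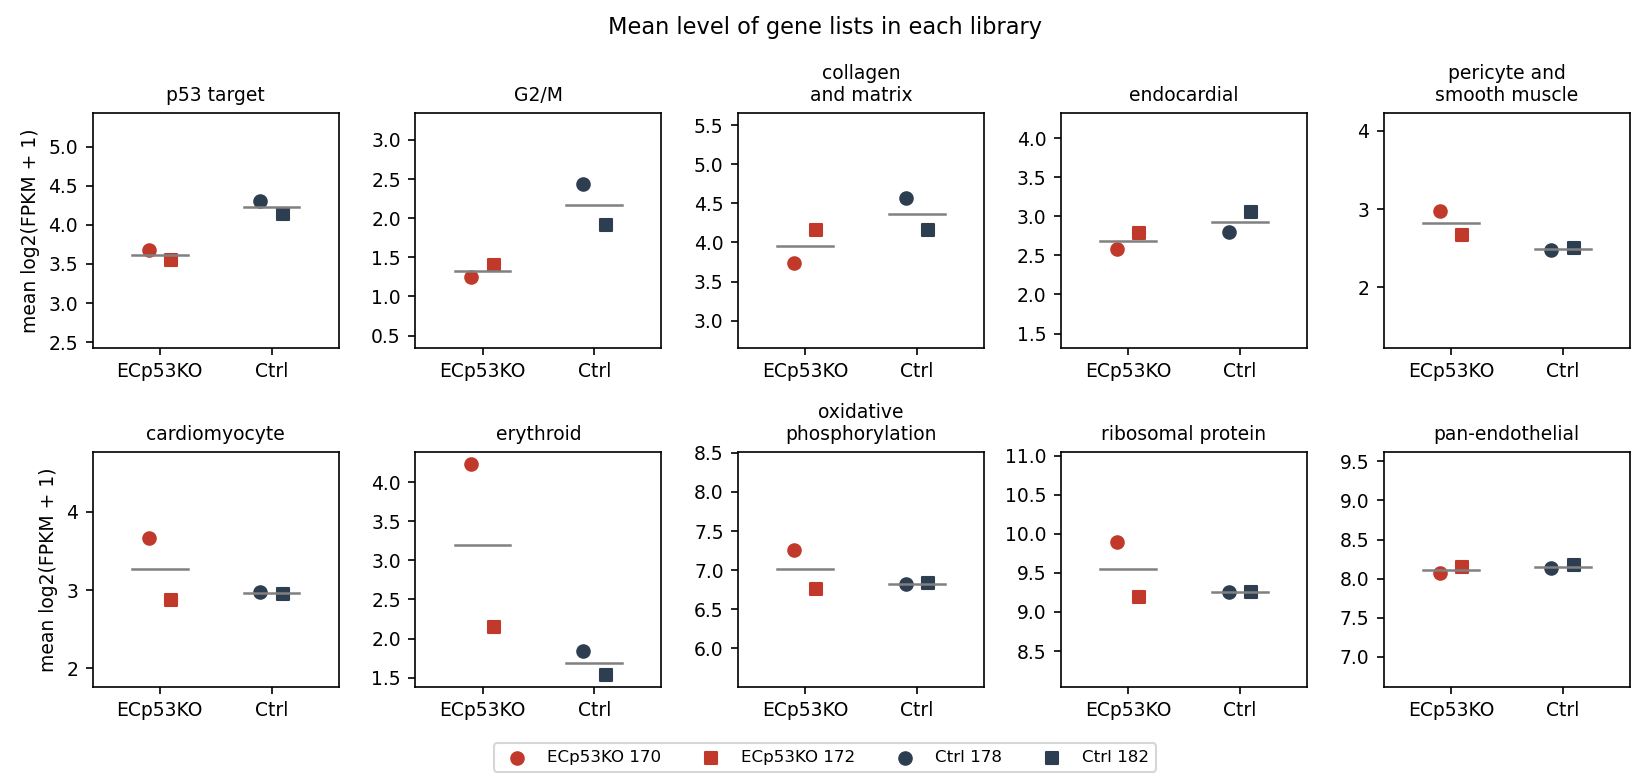
Mean of log2(FPKM + 1) over the members of 10 gene lists in each library (red ECp53KO, dark blue Ctrl), with a grey bar at the group mean and an axis of equal length in every panel. The p53 target genes lie at 3.68 and 3.55 in ECp53KO and 4.31 and 4.14 in Ctrl, and ECp53KO_170 stands above the other libraries for cardiomyocyte, erythroid, oxidative phosphorylation and ribosomal protein genes.

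Libraries of a group did not stand apart from those of the other over all genes. The Pearson correlation of log2(FPKM + 1) across genes, which are not independent replicates, was 0.904 within ECp53KO, 0.910 within Ctrl and 0.902 to 0.909 between groups. Without small RNA loci it was 0.972, 0.983 and 0.969 to 0.983. Each group held 1 library with Xist at over 23 FPKM (23.1 in ECp53KO_172 and 23.9 in Ctrl_182) and 1 with Xist near 0 (0.0230 in ECp53KO_170 and 0.0352 in Ctrl_178), and the Y-linked Ddx3y stood at 17.1 and 21.7 FPKM in the last 2, so sex as shown by these transcripts was balanced between the groups. In Ctrl_182 Ddx3y and Eif2s3y were at 0.912 and 1.21 FPKM, below the 21.7 and 27.5 FPKM of Ctrl_178 and above the 0.0422 and 0.0597 FPKM of ECp53KO_172.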

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

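The small RNA, transcript length and Xist alternatives were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. With Xist above 1 FPKM as a covariate, which sets libraries side by side by Xist level and not by number, Trp53 passed and Xaf1 was lost (limma adjusted p = 0.0208 and 0.0823). In place of 3 genes higher, 5 were called with a pseudocount of 0.1, 5 with robust shrinkage, 5 at an adjusted p under 0.1 and 1 with no filter. The counts with a fold of 2 as well were the same 5, 5 and 1 in the pseudocount, robust and unfiltered fits. Leaving out a library gave 1 to 21 genes higher and 12 to 58 lower, with the same ranges past a fold of 2. All 10 genes called lower over all genes were small RNA loci, so without such loci none of them was tested. In that fit 4 other genes were lower, and 4 past a fold of 2. Without small RNA loci and without ECp53KO_170, ECp53KO_172, Ctrl_178 and Ctrl_182 in turn, 5, 9, 12 and 6 genes were higher and 4, 12, 17 and 18 lower, all past a fold of 2. Of the p53 targets, 6 passed adjusted over the list alone, against 15 after rescaling to TPM, 11 with robust shrinkage, 14 with the length trend removed, 12 without small RNA loci (15, 10, 5 and 12 without each library in turn), and 1 to 6 on leaving out a library. Of the G2/M genes, 14 passed, against 3 at a mean of 5 FPKM or more (fewer genes tested), 23 without small RNA loci (15, 22, 0 and 26 without each library in turn), and 0 to 24 on leaving out a library. Apart from the cases with fewer genes or libraries, the cause was not tested.

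The p53 target list kept its call in 20 of 22 alternatives, with medians between -0.5 and -0.37. It lost the call with an estimated correlation in place of the preset one (median -0.38, adjusted p = 0.83). It also lost it with fry (-0.38, adjusted p = 0.245), which is a different test of the list. Since no list passed either test, these losses do not set the p53 target list apart. Trp53 lay between -3.62 and -2.79 in all 20 fits. It passed at -3.20 with robust shrinkage (limma adjusted p = 0.0412), without small RNA loci (0.0127) and with the Xist covariate. It also passed without small RNA loci and 1 library, at -3.53 without ECp53KO_170, -2.88 without ECp53KO_172, -2.79 without Ctrl_178 and -3.62 without Ctrl_182. Without ECp53KO_170, with and without small RNA loci, the direction of the test turned for oxidative phosphorylation (median -0.06), ribosomal protein (0.01) and cardiomyocyte genes (0.04), whose medians reached 0.48, 0.63 and 0.83 without ECp53KO_172. The oxidative phosphorylation call was also lost with the length trend removed (0.07, camera adjusted p = 0.198), and the endocardial call with no filter (-0.26, camera adjusted p = 0.0936). The other 29 lists, not called, stayed so in 595 of 633 cases, and 14 of them passed in at least 1 alternative. Of 2068 cases over 105 named genes, 2009 kept their side of the threshold, 52 passed newly and 7 were lost, all of Xaf1. Directions of results called in neither fit were not compared. The median of all genes was 0.01 as deposited, -0.09 after rescaling to TPM (a move of -0.107) and between 0 and 0.03 with the other scalings. Relative to the median of all genes, after rescaling and as deposited, p53 targets stood at -0.41 and -0.4, G2/M genes at -1.04 and -0.98, and oxidative phosphorylation genes at 0.16 and 0.17. With about 9900000 to 22500000 fragments, 1 fragment on a 2 kb transcript is worth 0.0222 to 0.0506 FPKM, which limits the precision of genes near the filter of 1 FPKM.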

Other observations

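The gene lists were tested as fixed in advance, and every test of an explanation given further on was chosen after its result was seen. Among signalling and stress lists, 0 passed the camera test. Interferon response genes had a median log2 fold change of 0.11 (37 measured, camera adjusted p = 0.103), with Xaf1 the only member that passed over all genes. Senescence-associated secretory genes had a median of -0.19 (20 measured, camera adjusted p = 0.0539), with Gdf15 passing over the list alone and the urokinase receptor gene Plaur at 17.2 ± 3.55 against 26 ± 3.22 FPKM. Unfolded protein and ATF4 response genes had a median of 0.12 and a mean of -0.05 (camera adjusted p = 0.6), with Sesn2 passing over the list alone. Camera adjusted p-values and medians were 0.307 and -0.03 for the BCL2 family and caspases, 0.553 and 0.12 for NF-kB and inflammatory genes, 0.105 and -0.15 for the Notch pathway, 0.391 and -0.12 for TGF-beta and BMP responses, and 0.144 and 0.11 for NRF2 and antioxidant genes. They were 0.495 and -0.04 for angiogenesis and tip cell genes, 0.307 and 0.09 for hypoxia and glycolysis, 0.495 and 0.02 for DNA repair, 0.515 and -0.05 for cholesterol synthesis, and 0.713 and -0.05 for MHC class II. Medians and tests differed in sign for RAS-MAPK output genes (median 0.05, mean -0.03, camera down, adjusted p = 0.821) and angiocrine factors (median 0.01, mean -0.06, camera down, adjusted p = 0.633). For immediate early and heat shock genes the median was -0.07 and the mean 0.01 (camera down, adjusted p = 0.657).

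Fatty acid uptake and oxidation genes had a median of -0.01 (24 measured, camera adjusted p = 0.495), and Angptl4, which encodes an inhibitor of lipoprotein lipase, stood at 13.8 ± 0.345 FPKM in ECp53KO and 28.4 ± 4.89 in Ctrl (SD, n = 2 each). Mesenchymal transition genes had a median of 0.12 (8 measured, camera adjusted p = 0.495), with Acta2 and Tagln, which the smooth muscle list also holds, passing over the list alone. Among arterial genes Alpl, which encodes alkaline phosphatase, stood at 136 and 127 against 75.2 and 84.1 FPKM. Medians of fibroblast (-0.14), macrophage and monocyte (-0.09), neutrophil (-0.16), platelet (0.43) and adipocyte genes (0.17) had camera adjusted p-values of 0.633, 0.515, 0.515, 0.235 and 0.633, over 11, 5, 3, 4 and 2 measured members. The adipocyte gene Car3 passed over its list alone (2.37 ± 0.557 against 0.728 ± 0.237 FPKM). Lymphocyte genes had 0 members at the filter and summed to 2.69, 0.164, 2.63 and 1.87 FPKM in ECp53KO_170 and ECp53KO_172 and Ctrl_178 and Ctrl_182. The Schwann and mesothelial lists had 1 measured member each, Cnp (log2 fold change 0.02) and Wt1 (-0.12).

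Genes with an unadjusted limma p under 0.01 were more frequent within 20 Mb of Trp53 on chromosome 11 (9 of 421 genes, 2.14%) than elsewhere (61 of 10651, 0.57%), but this window was examined because the called genes Xaf1, Tlcd2 and AA465934 lie in it. With the genes called in the fit over all genes or in that without small RNA loci removed, the shares were 1.44% (6 of 418) and 0.54% (58 of 10648, Fisher's exact p = 0.0333). Of 124 windows of 40 Mb without Trp53, 5 held a share as large. The windows were placed every 5 Mb, so they overlap and are not separate regions. Of the 9, 4 were higher (Xaf1, Aspa, Tlcd2 and AA465934) and 5 lower (Ltc4s, Usp43, Fam64a, Unc45b and Slfn5os, the last 2 overlapping and not told apart without strand). The nearest lies 1.73 Mb from Trp53, so an effect of the deletion limited to genes within 1 Mb would not reach these 9. This follows from their positions alone and does not show whether genes within 1 Mb differ. A candidate explanation is an interval of other strain origin linked to the targeted allele, which these counts leave open, and whether any of the 9 depends on p53 was not tested. The values do not single out ECp53KO_170 as the source and do not exclude it: with called genes and small RNA loci left out, the share in the window was 2.63% both with all libraries and without ECp53KO_170 (ECp53KO_172 then stands alone, assumed to vary like the controls), while the share elsewhere went from 1.32% to 1.61% and Fisher's exact p from 0.0319 to 0.113, against 0.105 without Ctrl_178, 0.0122 without Ctrl_182 and 0.0377 without ECp53KO_172, where the shares were 10.29% and 7.47%.

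The lower G2/M genes, with 30 of 30 members negative, may reflect fewer cycling endothelial cells in ECp53KO, a hypothesis that stays open because genes of the G1/S transition and DNA replication did not pass (median -0.08, camera adjusted p = 0.203, from 5.66e-05 to 0.987 over the alternatives) and because genotype cannot be separated from other differences between 2 and 2 libraries. Cycling leukocytes among the sorted control cells are argued against by the leukocyte lists, whose summed FPKM was 3.74 higher in Ctrl, against 87 for the G2/M genes (-1.87 against 53.3 without Ctrl_178, and 9.36 against 121 without Ctrl_182). The leukocyte genes Cd68 (0.702 and 0.307 against 4.31 and 1.08 FPKM) and, chosen after its values were seen, Cd52 (0.544 and listed at 0 against 2.55 and 0.828 FPKM) did not overlap between the groups, with Cd68 not past the test and Cd52 not tested. Cd68 also lies close to Trp53 on chromosome 11 (69664213 to 69666170), so its difference cannot be read as one of leukocytes alone. The depth of Ctrl_182 is argued against by the fit without it (median -1.21), and the transcript length trend of ECp53KO_170 by the fit with that trend removed (median -0.99). Sex is argued against because each group held 1 library with high Xist and 1 with high Y-linked transcripts. The call held with Xist above 1 FPKM as a covariate (camera adjusted p = 1.13e-20), but this adds no separate evidence, since that balance leaves the fold changes between groups as they were. Exact age and litter were not tested.

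The higher oxidative phosphorylation, ribosomal protein and cardiomyocyte genes rested on ECp53KO_170, in which FPKM fell with transcript length relative to the other libraries (Spearman's rho -0.43 across genes, which are not independent replicates, against 0.14 to 0.29). Members of these lists have short transcripts (median 1298, 1124 and 1318 nucleotides, against 3280 over all measured genes), and removing the trend lowered the median log2 shift of ECp53KO_170 from the other 3 libraries from 0.46 to 0.18, from 0.63 to 0.31 and from 0.69 to 0.52. The lower quartiles of the shifts stayed above 0 (0.08, 0.25 and 0.24). At the level of the groups, the oxidative phosphorylation call was lost with the trend removed (median log2 fold change 0.07, camera adjusted p = 0.198). The trend may be part of the cause. Whether it is the whole was not decided, since the length used, of the longest transcript, may differ from that of the transcript expressed. RNA of heart muscle stays open as a source for the oxidative phosphorylation genes, since the cardiomyocyte genes were also above the other libraries, by 247 FPKM in sum against 2190 FPKM for the oxidative phosphorylation genes, and the proportion of these in heart muscle was not measured here. A biological difference of the cells in ECp53KO_170 stays open and was not tested.

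Of 15 transcripts typical of liver, chosen after their values were seen, 12 were higher in both ECp53KO libraries than in either control and 3 overlapped (Ahsg, Fabp1 and Cyp3a11). Over all tested genes 19.1% were higher in this way, but a set chosen on its values cannot be compared with that share. Apoc1, named above by its small p, is among the 12. Ahsg stood at 11.1, 3.50, 5.50 and 12 FPKM in ECp53KO_170 and ECp53KO_172 and Ctrl_178 and Ctrl_182. In the same order, levels were 47.2, 26.2, 21.9 and 10.8 FPKM (Alb) and 29.3, 14.4, 11 and 5.38 FPKM (Apoa2). Alb and Apoa2 thus fell from library to library within each group too, as did the summed erythroid genes (464, 98.4, 69.1 and 42.3 FPKM). The Y-linked gene Ddx3y, at 17.1, 0.0422, 21.7 and 0.912 FPKM in these libraries, did not follow that order. The cause was not tested.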
